A study of Bos taurus with 54 samples.

How the data were processed

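The arrays measured total RNA from needle biopsies of the liver of Danish Holstein-Friesian cows in their first lactation. Live Escherichia coli had been infused into 1 front gland of the udder, which causes mastitis, and the liver was sampled 144 h before and 12, 24 and 192 h after the infusion. Each biopsy gave 1 Affymetrix bovine array. The 54 arrays came from 15 cows, with 14 arrays before infection, 14 at 12 h, 14 at 24 h and 12 at 192 h. The cow was the replicate, and arrays were paired by the cow numbers in the labels. No uninfected cows were sampled, so a change after infection also covers the passing of time, the stage of lactation and the earlier biopsies. The times 144 h before, 24 h and 192 h after infection lie whole days apart, and 12 h falls at another time of day.

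The deposited values are log2 expression values per probe set. Per the submitters' processing notes they came from RMA, with R 2.10.0, affy 1.24.2 and limma 3.2.1 named; other settings are not given in the sources used here. The values ran from 2.4 to 14.84. Array medians lay between 6.12 and 6.27. The standard deviation over probe sets lay between 2.21 and 2.39 on 53 arrays and was 1.55 on the array of cow 1112 before infection. The file held 24128 probe sets, of which 112 control probe sets were left out and 24016 were tested with no filter on level. Of these, 13292 carried 1 gene symbol in the annotation used here, 86 carried several and 10638 carried none. Together they named 9155 genes, 2913 of them by more than 1 probe set, and each gene was represented by its probe set with the highest mean over all arrays. Genome positions were not used.

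Changes were estimated with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table. One model held the time point and the cow as fixed terms, with moderated tests and no intensity trend. Cow 2105 had an array at 24 h alone and stayed out, which left 53 arrays of 14 cows and 36 residual degrees of freedom. Each time after infection was compared with the time before it, 24 h with 12 h and 192 h with 24 h. The numbers of cows with both arrays were 14 at 12 h, 13 at 24 h, 12 at 192 h, 13 for 24 h against 12 h and 11 for 192 h against 24 h. A moderated F test covered the 3 contrasts against the time before infection. P-values were adjusted by Benjamini-Hochberg over the 24016 probe sets of a contrast, and a probe set counted as changed at an adjusted p under 0.05. All tests were two-sided, and every change is on the log2 scale with its standard error (SE) unless a fold is stated. The number of arrays limits the precision.

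The pairing was examined on the values. After removal of the time means, 75 pairs of arrays from the same cow correlated with a median r of 0.26 (range −0.21 to 0.63) across probe sets, against −0.02 for pairs from different cows. The correlation within cows estimated by limma was 0.12.

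Gene lists of pathways and of cell type markers, 41 in all, were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Each list is named with its results. Lists were tested with camera, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over all lists and the 5 contrasts. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were the alternatives. By the rule, the named genes were the 10 with the largest increase and the 10 with the largest decrease in each contrast against the time before infection (5 and 5 in the later contrasts), with an adjusted p under 0.05 and the same sign in at least 80% of cows. Up to 3 members of each described list with the largest change past the threshold, the member with the highest level, and a fixed set of genes followed. HAMP and CPT1A of that set were not analysed here, and some genes that the rule names are not reported here. Symbols that are only locus numbers were passed over.

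RNA quality was followed by the difference between the 3 prime and 5 prime GAPDH control probe sets, which grows as RNA breaks down. It was 6.97 on the array of cow 1112 before infection and 0.04 to 3.42 on the others. That array correlated with the median array at r = 0.77, against at least 0.955 for any other array. It stayed in by the fixed design, and the numbers of changed probe sets are also given without it.

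For the counts, 13 other fits were run, besides leaving out each of the 14 cows and 2 other thresholds. They covered the cow block, the cows used, the variance model, array weights, a filter on level, median and quantile scaling, and centring on the ribosomal protein list. For the list tests 12 other settings were run, and for named genes the choice of probe set was changed. Of these alternatives, 3 fits and 8 list settings were chosen after seeing the data, among them those without the array of cow 1112 and without the 4 arrays with a GAPDH difference above 2. The steps were tested on simulated data at the size of the 24 h comparison. Of 250 probe sets shifted by 0.5, 67.6% were called, and of 250 shifted by 1, 95.6%; 34 of 118930 unshifted ones were called. A list of 30 genes shifted by 0.5 was called in 5 of 5 simulations by camera with either correlation and by fry. The simulated noise was independent between probe sets and the list members were drawn at random. The simulations therefore do not show how the list tests behave when genes of a list correlate.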

Results

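Liver biopsies from 15 cows were profiled before an E. coli infection of the udder and at 12, 24 and 192 h after it, to follow how the liver responds to an infection in another organ. The series held 14 arrays before infection, 14 at 12 h, 14 at 24 h and 12 at 192 h, and 11 cows had all 4 times. Arrays have no read depth; the median log2 value per array lay between 6.12 and 6.27. At some time after infection 14363 of 24016 probe sets changed (limma moderated F test), or 15751 without the array of cow 1112 before infection, whose RNA was degraded. The GAPDH difference between the 3 prime and 5 prime control probe sets was 1.17 ± 1.72 before infection (SD, n = 14) or 0.73 ± 0.43 without that array (n = 13). It was 0.91 ± 0.75 at 12 h (n = 14) and 0.65 ± 0.45 at 24 h (n = 14), and at 192 h it ran from 0.55 to 3.42 (n = 12).

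**Figure D1:**
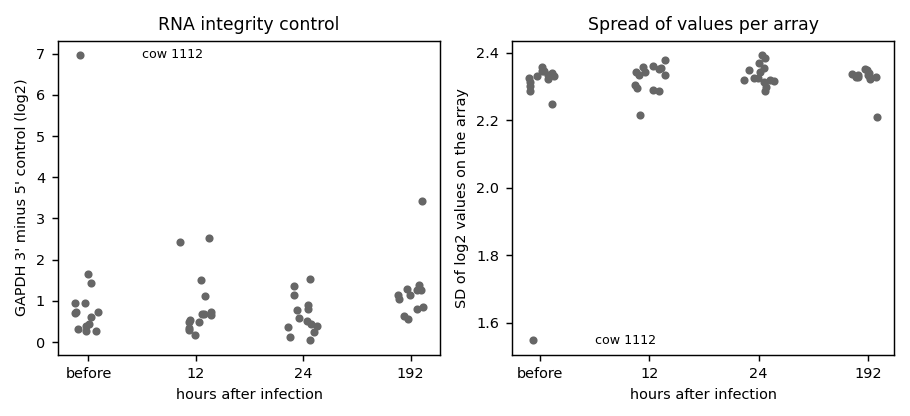
RNA quality and spread of values per array by time, with the log2 GAPDH 3 prime minus 5 prime difference on the left, the standard deviation of the log2 values over probe sets on the right, and 1 point per array. The array of cow 1112 before infection lies apart in both, with a GAPDH difference of 6.97 and a standard deviation of 1.55.

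The first comparison asked what had changed in the liver 12 h after infection. PTX3, a soluble pattern recognition protein, rose by 4.77 (SE 0.51, adjusted p = 2.19e-09, higher in 14 of 14 cows), from a mean of 3.09 ± 0.31 before infection (SD, n = 14) to 7.87 ± 2.80 (n = 14). The mean levels before infection of PTX3, CTSL (3.51), SPP1 (3.85) and LUM (3.92) lay near the lowest value in the file, 2.4, and were not shown to exceed background, so the sizes of their changes are not exact. SOCS3, an inhibitor of cytokine signalling, rose by 3.46 (SE 0.23) and the stress genes GADD45B and ATF3 by 3.44 (SE 0.18) and 3.81 (SE 0.29), each in 14 of 14 cows. Among the other leading increases were SLCO4A1, an organic anion transporter (3.94), RCAN1, an inhibitor of calcineurin (3.59), ZFAND2A (3.51) and the calcium binding proteins S100A12 (3.51) and S100A8 (3.32). CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 4.98 (SE 0.45, adjusted p = 3.55e-11) in 14 of 14 cows, from 9.15 ± 0.53 to 4.17 ± 2.13 (SD, n = 14 each). In most cows its 12 h value also lay near the lowest value in the file, so the size of this fall is not exact. The steroid-metabolising enzyme AKR1C3 fell by 3.37, the tight junction gene CLDN2 by 2.35, the lipogenic gene THRSP by 2.28 and ALAS1, the first enzyme of haem synthesis, by 2.12. HHEX (−2.12), IHH (−1.96), HDHD3 (−1.90), GPR37 (−1.86) and RHOJ (−1.84) completed the 10 largest decreases.

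Of all 9155 genes 1424 were higher and 1231 lower at 12 h. Of 24016 probe sets 6044 changed at 12 h (25.2%), 3078 higher and 2966 lower, with 595 higher and 211 lower by at least 2-fold. Without the array of cow 1112 before infection 7302 changed, 3316 higher and 3986 lower, with 544 higher and 251 lower by at least 2-fold. Centred on the ribosomal protein list, which shifted the median of all probe sets by −0.34, 2118 passed, 480 higher and 1638 lower; without that array the shift was 0.01, with 2873 higher and 3531 lower.

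Among the acute phase proteins, the plasma proteins that the liver releases in inflammation, 8 of 21 measured members rose at 12 h, 0 fell and 13 did not pass (9 higher adjusted over the list alone). The list was called higher (camera adjusted p = 0.000143, and adjusted p = 0.784 with an estimated correlation). HP, or haptoglobin, rose by 1.94 (SE 0.40), the serum amyloid SAA3 by 1.80 (SE 0.31) and LBP, which carries bacterial lipopolysaccharide, by 1.38 (SE 0.17), in 13, 12 and 13 of 14 cows. The degraded array of cow 1112 before infection enters these sizes, and in that cow HP went from 8.03 to 14.41. On the other arrays before infection HP ran from 9.48 to 13.95. CRP (0.50, adjusted p = 0.203) and ALB (−0.02, adjusted p = 0.793) did not pass. Of 32 genes of Toll-like receptor and NF-kB signalling 21 rose, 2 fell and 9 did not pass (22 higher and 3 lower adjusted over the list alone). BCL3 (2.30), NFKBIA (2.08) and BIRC3 (1.85) rose most, and the list was called higher (adjusted p = 7.2e-09, and adjusted p = 0.424 with an estimated correlation). The lipopolysaccharide coreceptor CD14 rose by 0.30, but did not pass with quantile scaling (0.14, adjusted p = 0.379), by its probe set of highest variance (0.20, adjusted p = 0.273) or with ribosomal centring (−0.05, adjusted p = 0.882). TLR4 (0.22, adjusted p = 0.248) passed without the array of cow 1112 before infection (0.36, adjusted p = 0.00167).

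Of 30 genes of IL-6 and JAK-STAT signalling 19 rose, 4 fell and 7 did not pass (19 higher and 5 lower adjusted over the list alone). SOCS3, FOS (3.06) and MYC (3.04) rose most, and the list was called higher (adjusted p = 2.65e-09, and adjusted p = 0.18 with an estimated correlation). Among 38 cytokines and chemokines 20 rose, 1 fell and 17 did not pass (21 higher and 1 lower adjusted over the list alone). This list was called higher (adjusted p = 6.79e-06, and adjusted p = 0.424 with an estimated correlation), although its median of 0.27 was −0.07 with ribosomal centring. The monocyte chemokine CCL2 rose by 2.73, the interleukin-1 antagonist IL1RN by 2.14, CXCL8 by 2.04, IL1B by 1.48 and IL10 by 0.92, the last not past the threshold with ribosomal centring (adjusted p = 0.137). IL6 (0.27, adjusted p = 0.0595) and TNF (0.10, adjusted p = 0.454) did not pass. IL6 passed without the array of cow 1112 before infection (0.35, adjusted p = 0.00229) and without cow 1415 (0.30, adjusted p = 0.0364) or cow 3141 (0.31, adjusted p = 0.0267). With all arrays it passed with median scaling (0.289, adjusted p = 0.0408), quantile scaling (0.315, adjusted p = 0.00417) and array weights (0.366, adjusted p = 0.00026).

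Heat shock proteins, which refold damaged proteins, rose in 23 of 27 measured members with 0 lower and 4 not passing (24 higher adjusted over the list alone). HSPH1 rose by 2.73, BAG3 by 2.22 and DNAJB1 by 2.15, and the list was called higher (adjusted p = 6.02e-11, and adjusted p = 0.671 with an estimated correlation). Genes of endoplasmic reticulum stress and secretion rose in 25 of 42 members, with 0 lower and 17 not passing (26 higher adjusted over the list alone), led by ATF3 and the chaperone genes HYOU1 (2.00) and CRELD2 (1.95). That list was called higher (adjusted p = 1.1e-09, and adjusted p = 0.702 with an estimated correlation), and its change differed between cows, from −0.09 in cow 1415 to 1.05 (mean 0.45, SE 0.12, without cow 1112). Of 27 genes of apoptosis and survival 11 rose, 3 fell and 13 did not pass (11 higher and 3 lower adjusted over the list alone). GADD45B, BIRC3 and GADD45A (1.66) rose most. The list was called higher, with a median of 0.23 that was −0.11 with ribosomal centring (adjusted p = 0.000741, and adjusted p = 0.624 with an estimated correlation).

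The bile acid list was called lower at 12 h, with 1 of 21 members higher, 8 lower and 12 not passing (1 higher and 9 lower adjusted over the list alone). Its adjusted p = 0.00749, and adjusted p = 0.85 with an estimated correlation. Besides CYP7A1, the liver transcription factor HNF4A fell by 1.58 and KLB, a coreceptor that represses CYP7A1, by 1.53. Of 42 cell cycle genes 5 fell, 0 rose and 37 did not pass (4 lower adjusted over the list alone), and the list was called lower (adjusted p = 0.0191, and adjusted p = 0.976 with an estimated correlation). The share of its members that fell did not exceed that of all genes, 1231 of 9155. TPX2 (−0.69), GMNN (−0.54) and TYMS (−0.52) fell most, and none of these 3 passed in a fit of the 2 times alone (adjusted p 0.0559 to 0.0666). Of 18 neutrophil markers 7 rose, 0 fell and 11 did not pass (7 higher adjusted over the list alone). S100A12, S100A8 and S100A9 (2.55) rose most, and the list was called higher with a median of 0.07, or −0.27 with ribosomal centring (adjusted p = 0.0171, and adjusted p = 0.828 with an estimated correlation).

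Of 17 iron handling genes 3 rose, HP, SLC11A2 (1.85) and SLC39A14 (0.65, not past the threshold with ribosomal centring), 0 fell and 14 did not pass (3 higher adjusted over the list alone). Of 63 ribosomal proteins 0 changed, also when adjusted over the list alone. Both lists were called higher at 12 h (adjusted p = 0.0332 and 0.0039, and adjusted p = 0.87 and 0.976 with an estimated correlation). Their medians of 0.20 and 0.32 were −0.14 and −0.02 with ribosomal centring, and both calls ended without the array of cow 1112 before infection (adjusted p = 0.219 and 0.546). On that array the ribosomal median differed by −4.42 from the median of the other arrays before infection. Without it 5 further lists were called lower at 12 h: drug and xenobiotic metabolism (adjusted p = 0.00186), hepatocyte markers (0.00766), the mitochondrial respiratory chain (0.0206), fatty acid and triglyceride synthesis (0.0209) and fatty acid oxidation (0.0234). With an estimated correlation 0 lists were called without that array (lowest adjusted p = 0.141).

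**Figure D2:**
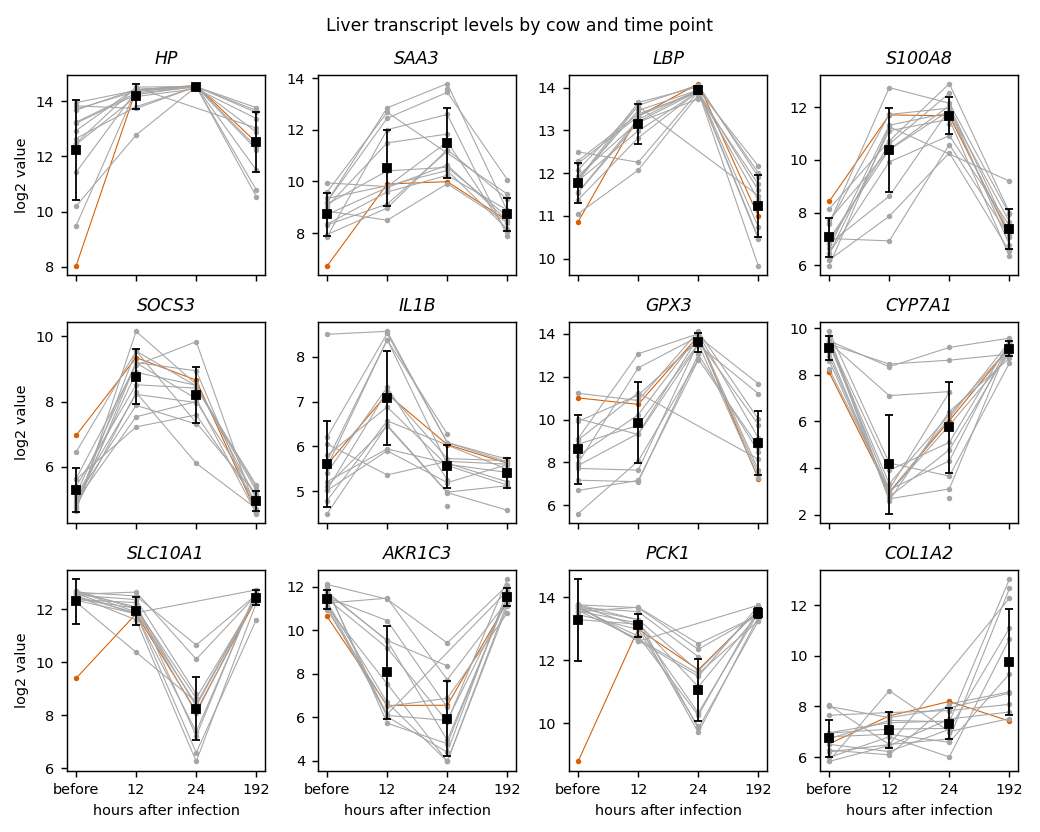
Log2 expression of 12 genes before infection and at 12, 24 and 192 h, where grey lines are single cows, the orange line is cow 1112 and black squares are means ± SD. HP, SAA3, LBP and S100A8 stood highest at 24 h, IL1B and SOCS3 at 12 h and COL1A2 at 192 h, while CYP7A1 stood lowest at 12 h and AKR1C3, SLC10A1 and PCK1 at 24 h.

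The next comparison asked which changes were present at 24 h, when 13 cows had both arrays. TNFRSF6B, a decoy receptor of the TNF receptor family, rose by 5.58 (SE 0.25, adjusted p = 5.3e-20, 13 of 13 cows), from 4.75 ± 0.27 to 10.35 ± 0.79 (SD, n = 14 each). GPX3, the plasma glutathione peroxidase, rose by 5.02 (SE 0.44), S100A12 by 4.93 (SE 0.32), S100A8 by 4.70 (SE 0.32) and the lysosomal protease CTSL by 4.25 (SE 0.40), each in 13 of 13 cows. HOPX (4.16), ANKRD1 (3.66), S100A9 (3.62), the cadherin CDH11 (12.2-fold) and RFLNA (3.51) followed. AKR1C3 fell by 5.39 (SE 0.44, adjusted p = 2.68e-13, 13 of 13 cows), from 11.42 ± 0.43 to 5.93 ± 1.73. The carbonic anhydrase CA3 fell by 4.55, the bile acid uptake transporter SLC10A1 by 4.03, and the drug-metabolising enzymes FMO1, UGT2B10 and FMO5 stood at −3.87, −3.86 and −3.69. The prolactin receptor PRLR (−3.68), the transporter SLCO2B1 (−3.37), urate oxidase UOX (−3.32) and the fatty acid desaturase FADS2 (−3.28) were the other leading decreases.

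At 24 h 10674 probe sets changed (44.4%), 5812 higher and 4862 lower, with 936 higher and 918 lower by at least 2-fold; without the array of cow 1112 before infection 11195 changed, 6062 higher and 5133 lower, with 767 higher and 1058 lower by at least 2-fold. Of all 9155 genes 3177 were higher and 1748 lower at 24 h. Centred on the ribosomal proteins, which shifted the median of all probe sets by −0.77, 17760 probe sets passed, 471 higher and 17289 lower. Without that array the shift was −0.40, with 1936 higher and 17592 lower. The ribosomal list itself was called higher at 24 h, with 47 of 63 members higher, 0 lower and 16 not passing (54 higher adjusted over the list alone). RPL4 rose by 1.22 (adjusted p = 0.0834 in a fit of the 2 times alone) and RPL7A by 1.06 (adjusted p = 0.052 with ribosomal centring), or by 0.65 and 0.63 without the array of cow 1112. Its median of 0.68, or 0.38 without the array of cow 1112, was −0.09 when centred on itself (adjusted p = 0.00033, and adjusted p = 0.976 with an estimated correlation).

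Lists of liver metabolism were called lower at 24 h. In bile acid synthesis and transport 19 of 21 members fell, 0 rose and 2 did not pass (19 lower adjusted over the list alone). SLC10A1, SLCO2B1 and CYP7A1 (−3.20) fell most, and the list median was −1.54 (adjusted p = 1.64e-10, and adjusted p = 0.424 with an estimated correlation). In drug and xenobiotic metabolism 27 of 36 fell, 1 rose and 8 did not pass (1 higher and 28 lower adjusted over the list alone). FMO1, UGT2B10 and FMO5 led these, with a list median of −1.15 (adjusted p = 8.41e-10, and adjusted p = 0.702 with an estimated correlation). In amino acid catabolism and the urea cycle 29 of 46 fell, 4 rose and 13 did not pass (6 higher and 29 lower adjusted over the list alone; adjusted p = 7.4e-08, and adjusted p = 0.702 with an estimated correlation). FTCD of histidine breakdown fell by 2.29, while GNMT, which uses methyl groups from methionine, and the serine dehydratase SDS rose by 3.38 and 2.29. The urea cycle enzyme CPS1 (−0.07, adjusted p = 0.556) passed without cow 1112 (−0.19, adjusted p = 0.00856).

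In fatty acid oxidation and ketogenesis 22 of 35 members fell, 2 rose and 11 did not pass (2 higher and 22 lower adjusted over the list alone). ECI1 (4.29-fold lower), CYP4A11 (−1.84) and the fatty acid binding protein FABP1 (−1.59) fell most (list adjusted p = 2.05e-07, and adjusted p = 0.702 with an estimated correlation). In fatty acid and triglyceride synthesis 16 of 33 fell, 5 rose and 12 did not pass (6 higher and 18 lower adjusted over the list alone). FADS2, THRSP (−3.03) and the desaturase SCD (−2.39) fell most (list adjusted p = 0.000863, and adjusted p = 0.702 with an estimated correlation). In cholesterol synthesis and uptake 13 of 19 fell, 2 rose and 4 did not pass (2 higher and 13 lower adjusted over the list alone). TM7SF2 fell by 2.39 and DHCR7 by 1.77, while PMVK rose by 2.24 (list adjusted p = 6.1e-05, and adjusted p = 0.778 with an estimated correlation). In gluconeogenesis 15 of 24 fell, 3 rose and 6 did not pass (3 higher and 15 lower adjusted over the list alone; adjusted p = 0.000343, and adjusted p = 0.778 with an estimated correlation). The triokinase TKFC fell by 2.93, the glucose-6-phosphate transporter SLC37A4 by 2.66 and PCK1, a rate-controlling enzyme of glucose synthesis, by 2.15 (SE 0.32).

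Of 23 hepatocyte markers 12 fell, 1 rose and 10 did not pass (1 higher and 13 lower adjusted over the list alone). UGT2B10, CYP2E1 (−2.21) and PIPOX (−1.71) fell most, and the list was called lower (median −0.46, adjusted p = 0.00117, and adjusted p = 0.87 with an estimated correlation). Without the array of cow 1112 before infection 22 were lower and the median was −0.73. Of 20 negative acute phase proteins, plasma proteins that fall in inflammation, 7 were lower, 1 higher and 12 did not pass (1 higher and 7 lower adjusted over the list alone). The list was called lower (median −0.33, adjusted p = 0.0088, and adjusted p = 0.976 with an estimated correlation), and 19 were lower without that array. SERPINA6, IGFALS and HRG stood at −1.89, −1.88 and −1.86. ALB fell by 0.17 (adjusted p = 0.000513), from a level of 14.65 ± 0.11 (SD, n = 14) near the highest value of any array, 14.84. ALB did not pass with an intensity trend (adjusted p = 0.219) or by the mean of its probe sets (adjusted p = 0.0762), and its probe set of highest variance gave 0.28 (adjusted p = 0.496). IGF1 fell by 0.25 (adjusted p = 0.0104). It did not pass with cows that had all 4 times (adjusted p = 0.122) or by the mean of its probe sets (adjusted p = 0.47), and its probe set of highest variance gave 0.05 (adjusted p = 0.854). Over the 12 cows without cow 1112 the medians of bile duct, T and NK cell and stellate cell markers differed by −0.07 (SE 0.06), −0.14 (SE 0.06) and 0.11 (SE 0.06), and the GAPDH difference by −0.04 (SE 0.14).

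The acute phase list was not called at 24 h: 9 of 21 members were higher, 2 lower and 10 did not pass (10 higher and 2 lower adjusted over the list alone; adjusted p = 0.18). PTX3 rose by 3.11, SAA3 by 2.71 (SE 0.32) and LBP by 2.19 (SE 0.18), the last 2 in 13 of 13 cows. HP rose by 2.33, or by 2.00 without the array of cow 1112 before infection. It stood at 14.17 ± 0.47 at 12 h and 14.52 ± 0.02 at 24 h (SD, n = 14 each), so close to the highest value of any array, 14.84, that the sizes of its changes are not exact. CRP rose by 0.81 (adjusted p = 0.019), or by 0.41 (adjusted p = 6.67e-08) without that array, which was 0.04 (adjusted p = 0.766) with ribosomal centring and −0.02 with both. In a fit of the 2 times alone it did not pass (adjusted p = 0.112). Endoplasmic reticulum stress and secretion genes rose in 36 of 42 members, with 0 lower and 6 not passing (37 higher adjusted over the list alone). CRELD2 (2.65), HYOU1 (2.24) and MANF (2.12) rose most, and the list was called higher (median 1.17, adjusted p = 3.61e-09, and adjusted p = 0.716 with an estimated correlation). Of 29 proteasome genes 28 rose, 0 fell and 1 did not pass (28 higher adjusted over the list alone). PSMB5 rose by 1.17 and PSMB4 by 1.01, the latter not past the threshold with ribosomal centring (adjusted p = 0.151). The list was called higher, and its median of 0.71 was −0.06 with ribosomal centring (adjusted p = 1.8e-06, and adjusted p = 0.716 with an estimated correlation).

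Of 30 IL-6 and JAK-STAT signalling genes 21 rose, 3 fell and 6 did not pass at 24 h (21 higher and 3 lower adjusted over the list alone). SOCS3 (2.90) and the interleukin-1 receptors IL1R2 (2.65) and IL1R1 (1.75) rose most. This list was called higher, and its median of 0.75 was −0.02 with ribosomal centring (adjusted p = 0.00263, and adjusted p = 0.702 with an estimated correlation). Cytokines and chemokines were not called, with 6 higher, 5 lower and 27 not passing (5 higher and 4 lower adjusted over the list alone, list adjusted p = 0.368). Toll-like receptor and NF-kB signalling was not called either, with 12 higher, 3 lower and 17 not passing (13 higher and 3 lower adjusted over the list alone, list adjusted p = 0.242). TNF fell by 0.31 and CD14 by 0.36, the latter not past the threshold by its probe set of highest variance (adjusted p = 0.0606). IL1B (−0.02), IL10 (−0.19), CXCL8 (0.59) and IL6 (0.03) did not pass, and neither did TLR4 (−0.15). With ribosomal centring, which shifted the median of all probe sets by −0.77, 4 of these passed as lower. They were IL1B (−0.785, adjusted p = 0.0269), IL10 (−0.962, adjusted p = 0.00208), IL6 (−0.743, adjusted p = 0.0342) and TLR4 (−0.915, adjusted p = 0.0203). CCL2 rose (adjusted p = 0.0461, 11 of 13 cows) but did not pass without the array of cow 1112 before infection (0.93, adjusted p = 0.0693). Of 37 interferon-stimulated genes 11 fell, 3 rose and 23 did not pass (3 higher and 11 lower adjusted over the list alone). IFI6 (−1.07), DHX58 (−1.04) and IFI44 (−0.81) fell most, and the list was called lower (adjusted p = 0.0277, and adjusted p = 0.923 with an estimated correlation). Cell cycle genes were called lower (adjusted p = 0.0348, and adjusted p = 0.976 with an estimated correlation), with 8 of 42 lower, 1 higher and 33 not passing (1 higher and 8 lower adjusted over the list alone). The share lower did not exceed that of all genes, 1748 of 9155. Cyclin CCND1 fell by 1.22, and MCM6 rose by 0.83, which did not pass with ribosomal centring (adjusted p = 0.846).

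Skeletal muscle markers were called lower at 24 h (7 of 22 lower, 1 higher and 14 not passing, 1 higher and 6 lower adjusted over the list alone, adjusted p = 0.0292, and adjusted p = 0.791 with an estimated correlation). Of these CA3 stood at a mean of 11.21 over all arrays, and CKM, the muscle creatine kinase, rose by 2.24. This call ended without the array of cow 1112 before infection (adjusted p = 0.0503), and 3 lists were gained. Complement genes were then lower (15 of 26 lower, 4 higher; adjusted p = 0.000325), and heat shock proteins (adjusted p = 0.0474) and apoptosis and survival genes (adjusted p = 0.0485) higher, and with an estimated correlation 0 lists were called without that array (lowest adjusted p = 0.141). With all arrays the heat shock list had 16 of 27 higher (adjusted p = 0.0559).

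**Figure D3:**
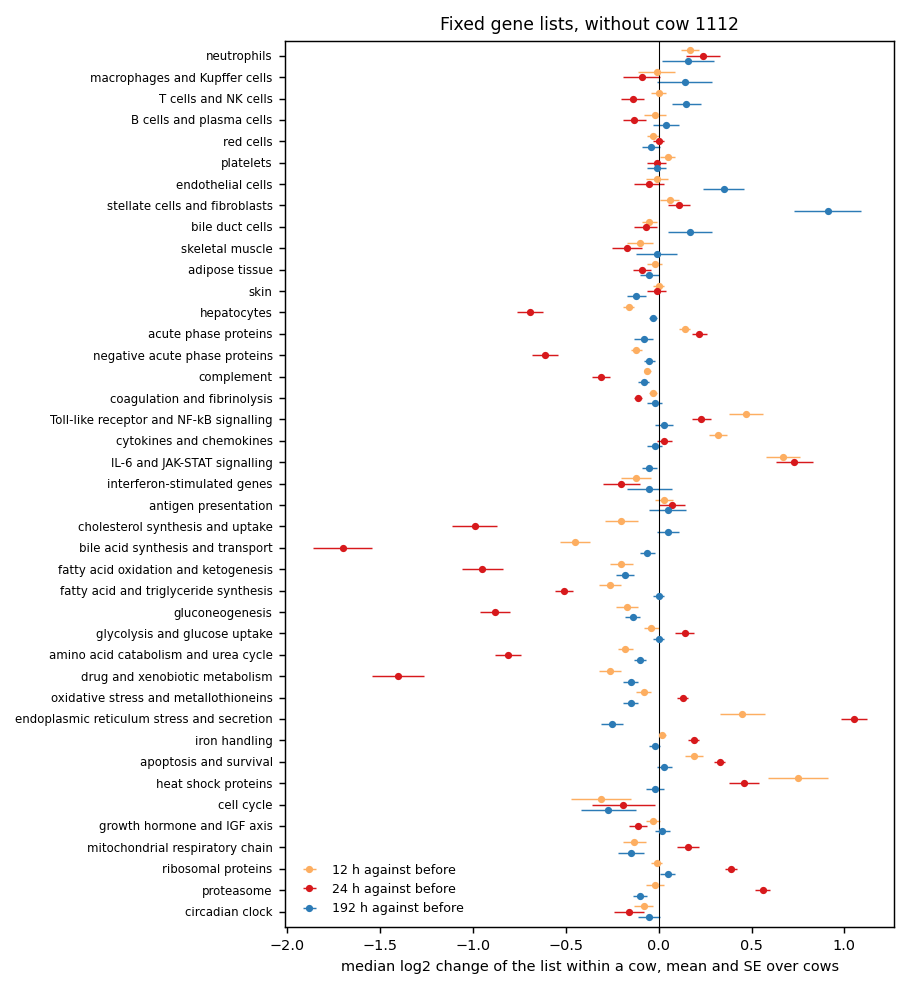
Mean change of gene list medians within cows, in log2 against the time before infection, with the SE over cows without cow 1112, at 12 h (orange-yellow), 24 h (red) and 192 h (blue). Endoplasmic reticulum genes stood at 0.45 (12 h), 1.05 (24 h) and −0.25 (192 h), hepatocyte markers at −0.16, −0.69 and −0.03, and stellate cell and fibroblast markers at 0.91 at 192 h. With all arrays and ribosomal centring, the 12 h medians of the cytokine, apoptosis, neutrophil, iron and ribosomal lists and the 24 h medians of the IL-6, proteasome and ribosomal lists turned from above to below 0. Those medians include the degraded array of cow 1112 before infection, which the figure leaves out. Centring shifted the median of all probe sets by −0.34 at 12 h and −0.77 at 24 h with that array. Without it these shifts were 0.01 and −0.40.

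At 192 h, 8 days after infection, fewer probe sets passed the threshold than at 12 or 24 h. COL1A2, a chain of type I collagen, rose by 3.02 (SE 0.46, adjusted p = 4.2e-05, 12 of 12 cows), which is 8.13-fold on average. The size of this rise differed widely between cows. COL1A2 went from 7.649 to 8.078 in cow 1867 and from 6.724 to 13.027 in cow 1289. Its SD over arrays was 0.73 before infection (n = 14) and 2.1 at 192 h (n = 12). The SE comes from the model over all times and does not show this spread. Dermatopontin DPT and the collagen COL3A1 rose by 2.29 (SE 0.31) and 2.26 (SE 0.31), each in 12 of 12 cows. The matrix gene LUM rose by 1.76, connexin GJA1 by 1.53, COL6A1 by 1.51, the growth factor PTN by 1.51, complement C7 by 1.51 and SPARC, a collagen-binding protein, by 1.43. These 6 did not pass with ribosomal centring of all arrays (1.03 to 1.36, adjusted p 0.0626 to 0.135), which shifted the median of all probe sets by −0.40. With centring and without the array of cow 1112 before infection the shift was −0.04, and all 6 kept their calls. SPP1, or osteopontin, rose by 1.49 (adjusted p = 0.0276), a call that ended without cow 1289, 1385, 1415, 1920 or 1922 (1.20 to 1.50, adjusted p 0.0505 to 0.08), without the cow block, with cows that had all 4 times or with ribosomal centring (adjusted p 0.0648 to 0.264). The largest decreases were smaller: FOLR3 (−1.06), the chaperone CALR (−1.03, SE 0.19, 12 of 12 cows), apolipoprotein APON (−0.86), the tocopherol transfer protein TTPA (−0.85), SAR1B (−0.82), HM13 (−0.81), URAD (−0.80), ALDH6A1 (−0.80), ABCF3 (−0.77) and CYP4A22 (−0.77). Of these 10 only CALR passed without the cow block (adjusted p 0.068 to 0.277 for the others). FOLR3, APON, TTPA and ALDH6A1 did not pass with a random block (adjusted p 0.0836 to 0.145), APON and ALDH6A1 with the 2 times alone (0.0548 and 0.058), TTPA and ALDH6A1 with cows that had all 4 times (0.0687 and 0.135), or SAR1B and ABCF3 with ribosomal centring (0.0582 and 0.0994), where their falls were larger (−1.22 and −1.18). TTPA did not pass without cow 1920 or 1922 (−0.76 and −0.75, adjusted p = 0.0521 and 0.0524), nor ALDH6A1 without cow 1385, 1920, 1922 or 3341 (−0.77 to −0.67, adjusted p 0.0526 to 0.0962).

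Of all 9155 genes 639 were higher and 316 lower at 192 h. At 192 h 2464 probe sets changed (10.3%), 1568 higher and 896 lower, with 85 higher and 13 lower by at least 2-fold, or 3214 without the array of cow 1112 before infection, 1778 higher and 1436 lower, with 75 higher and 24 lower by at least 2-fold. The GAPDH difference rose by 0.59 (SE 0.17) over the 11 cows without cow 1112, in 9 of them. Without the cow block 494 passed, 416 higher and 78 lower, and 1409 without cow 1922 or 1605 without cow 1920. Array weights gave 5716, 2924 higher and 2792 lower, and leaving out the 4 arrays with a GAPDH difference above 2 gave 3803, 1990 higher and 1813 lower. Centred on the ribosomal proteins, with a shift of −0.40, 99 passed, 13 higher and 86 lower; without the array of cow 1112 the shift was −0.04, with 950 higher and 1649 lower.

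Markers of stellate cells and fibroblasts, the collagen-producing cells of the liver, rose at 192 h in 15 of 20 measured members, with 0 lower and 5 not passing (17 higher adjusted over the list alone). The list was called higher with a median of 0.88 (adjusted p = 6.64e-14, and adjusted p = 0.18 with an estimated correlation). Within cows its median rose in 11 of 11 cows without cow 1112, by at least 0.10 (mean 0.91, SE 0.18). Of 19 endothelial markers 10 rose, 0 fell and 9 did not pass (13 higher and 1 lower adjusted over the list alone). EMCN rose by 0.71 and ERG by 0.61, and the list was called higher (adjusted p = 6.13e-06, and adjusted p = 0.624 with an estimated correlation). EMCN and ERG did not pass with ribosomal centring (adjusted p = 0.389 and 0.512), nor did ERG without the cow block (adjusted p = 0.15), with cow as a random block (adjusted p = 0.056) or by the mean of its probe sets (adjusted p = 0.0538). Beside these lists, the medians of bile duct, macrophage, and T and NK cell markers differed by 0.17 (SE 0.12), 0.14 (SE 0.15) and 0.15 (SE 0.08) within cows. Those of skin, skeletal muscle and adipose markers differed by −0.12 (SE 0.05), −0.01 (SE 0.11) and −0.05 (SE 0.05), and the hepatocyte median by −0.03 (SE 0.02).

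Of 42 cell cycle genes 4 fell at 192 h, 0 rose and 38 did not pass (4 lower adjusted over the list alone), and the list was called lower (adjusted p = 2.99e-05, and adjusted p = 0.791 with an estimated correlation). The cyclin CCNE1 fell by 0.32 and MAD2L1 by 0.60. CCNE1 did not pass without the cow block, with the 2 times alone, with cows that had all 4 times, with quantile scaling or ribosomal centring, or by its probe set of highest variance (adjusted p 0.0715 to 0.197), although centring made its fall larger. MAD2L1 did not pass without the block, with a random block, with the 2 times alone, with cows that had all 4 times or with ribosomal centring, where its fall was also larger (adjusted p 0.0882 to 0.196), nor without cow 1922, 1981 or 3141 (−0.59 to −0.51, adjusted p 0.0501 to 0.0556). Endoplasmic reticulum genes were called lower, with 3 of 42 lower, among them CALR and EDEM2 (−0.38, or adjusted p = 0.201 without the cow block), 0 higher and 39 not passing (3 lower adjusted over the list alone). The list had an adjusted p = 0.0316, and adjusted p = 0.976 with an estimated correlation, and 15 members were lower without the array of cow 1112 before infection (adjusted p = 1.73e-06). Skin markers (1 of 11 lower, 0 higher, 10 not passing, 2 lower adjusted over the list alone, adjusted p = 0.00749, and adjusted p = 0.671 with an estimated correlation) were no longer called without that array (adjusted p = 0.0624). Ribosomal proteins were called higher, with 2 of 63 higher, 0 lower and 61 not passing (2 higher adjusted over the list alone, adjusted p = 1.71e-05, and adjusted p = 0.976 with an estimated correlation). The share higher did not exceed that of all genes, 639 of 9155. The ribosomal median was 0.39 with all arrays, 0.04 without that array and −0.01 with ribosomal centring.

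Without the array of cow 1112 before infection 6 more lists were called at 192 h, and 0 with an estimated correlation (lowest adjusted p = 0.141). The mitochondrial respiratory chain (19 of 70 lower and 0 higher, adjusted p = 1.47e-07), fatty acid oxidation (adjusted p = 0.000376), the proteasome (adjusted p = 0.01), drug metabolism (adjusted p = 0.0132) and oxidative stress genes (adjusted p = 0.0383) were lower. Bile duct markers were higher (adjusted p = 0.0259). The acute phase list was not called at 192 h (0 of 21 higher, 1 lower, 20 not passing, 0 adjusted over the list alone, adjusted p = 0.605). HP (0.32), SAA3 (−0.01), SOCS3 (−0.43), CYP7A1 (0.11), PCK1 (0.24) and TNF (−0.25, adjusted p = 0.0714) did not pass. The degraded array of cow 1112 before infection enters these values. In that cow PCK1 went from 8.79 to 13.59, HP from 8.03 to 12.50 and SOCS3 from 6.96 to 4.61. In most other cows PCK1 stood lower at 192 h than before infection. TNF passed without cow 1867 (−0.30, adjusted p = 0.0236), with array weights (−0.267, adjusted p = 0.0132) and without the 4 arrays with a GAPDH difference above 2 (−0.294, adjusted p = 0.0205). LBP stood at −0.57 (adjusted p = 0.0358), lower in 7 of 12 cows, and did not pass without cow 1289, 1385, 1867, 1922, 1981 or 3141 (−0.57 to −0.45, adjusted p 0.0632 to 0.11). Nor did it pass without the cow block, with a random block, with the 2 times alone, with cows that had all 4 times, with an intensity trend or with ribosomal centring (−0.97 to −0.54, adjusted p 0.0504 to 0.153).

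**Figure D4:**
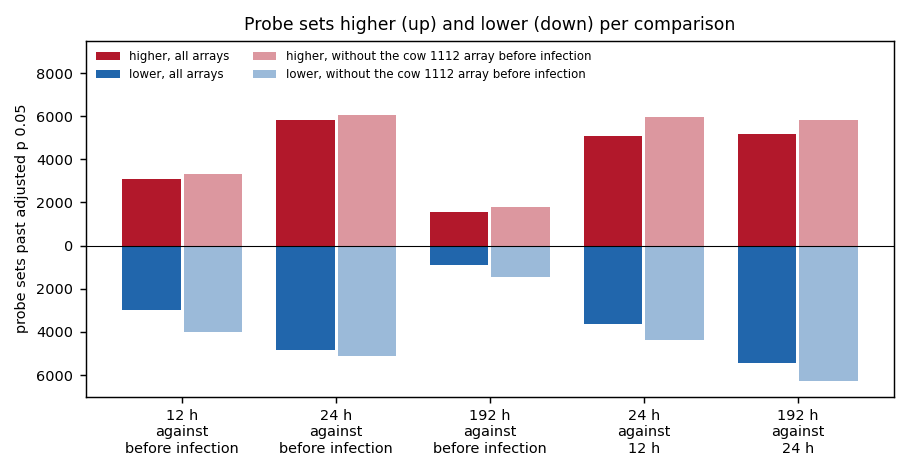
Probe sets past the threshold in each of the 5 comparisons, higher (red, upwards) and lower (blue, downwards), with all arrays (dark) and without the array of cow 1112 before infection (pale). With all arrays 6044 changed at 12 h, 10674 at 24 h and 2464 at 192 h, 8736 between 12 and 24 h and 10605 between 24 and 192 h, and the side of 50% on which the share higher lay turned with ribosomal centring in each of the 5. Without the array of cow 1112 before infection it did not turn at 12 h, with 45.4% higher before centring and 44.9% after.

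A direct test compared 24 h with 12 h in 13 cows. TNFRSF6B, CTSL and GPX3 rose by 4.23, 4.15 and 3.77 and CLDN2 and PDZK1IP1 by 2.91 and 2.86, each in 13 of 13 cows (adjusted p at most 4.33e-08). CA3 (−4.43), FMO1 (−3.93), SLC10A1 (−3.68), UOX (−3.32) and FMO5 (−3.32) fell most, each in 13 of 13 cows (adjusted p at most 4.48e-09). IL1B (−1.50), CXCL8 (−1.45) and IL10 (−1.11) fell from their 12 h levels, and SAA3 and LBP rose further by 0.91 and 0.81. CYP7A1 stood higher than at 12 h, when most of its values lay near the lowest value in the file, as did those of CTSL.

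Of all 9155 genes 2768 were higher at 24 h than at 12 h and 1395 lower. Between 12 and 24 h 8736 probe sets changed (36.4%), 5084 higher and 3652 lower, or 10348 without the array of cow 1112 before infection, 5950 higher and 4398 lower. Ribosomal centring, with a shift of −0.43, left 4010, 305 higher and 3705 lower. Without that array 1578 were higher and 17541 lower at a shift of −0.42.

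Of 36 drug metabolism genes 28 were lower at 24 h than at 12 h, 2 higher and 6 did not pass (2 higher and 28 lower adjusted over the list alone), with UGT2B10 at −2.80. Of 46 genes of amino acid catabolism 26 were lower, 3 higher and 17 did not pass (4 higher and 26 lower adjusted over the list alone), with FTCD at −2.04 and KMO at −1.95. Fatty acid oxidation had 22 of 35 lower, 3 higher and 10 not passing (3 higher and 22 lower adjusted over the list alone), with ECI1 at −2.19. Bile acid genes had 15 of 21 lower, 3 higher and 3 not passing (3 higher and 15 lower adjusted over the list alone), with SLC27A2 at −2.48. These 4 lists were called lower (adjusted p 7.99e-11, 4.02e-09, 9.7e-09 and 7.14e-08), with an adjusted p = 0.702, 0.671, 0.671 and 0.664 with an estimated correlation.

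Cholesterol genes had 14 of 19 lower than at 12 h, 1 higher and 4 not passing (2 higher and 14 lower adjusted over the list alone), with TM7SF2 at −1.89. Gluconeogenesis had 14 of 24 lower, 1 higher and 9 not passing (1 higher and 14 lower adjusted over the list alone), with TKFC at −2.57. Of 20 negative acute phase proteins 10 were lower, 0 higher and 10 did not pass (10 lower adjusted over the list alone), with HRG at −2.03. Of 23 hepatocyte markers 11 were lower, 2 higher and 10 did not pass (2 higher and 11 lower adjusted over the list alone), with CYP2E1 at −2.49. Fatty acid and triglyceride synthesis had 12 of 33 lower, 6 higher and 15 not passing (6 higher and 13 lower adjusted over the list alone), with FADS2 at −3.17. These 5 lists were called lower (adjusted p 1.76e-05, 1.17e-05, 0.000237, 0.00042 and 0.011), with an adjusted p = 0.726, 0.702, 0.85, 0.851 and 0.784 with an estimated correlation.

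Among cytokines and chemokines 19 of 38 were lower than at 12 h, 2 higher and 17 did not pass (3 higher and 19 lower adjusted over the list alone). CXCL10 (−2.85), CCL4 (−2.35) and CCL8 (−1.91) fell most, and the list was called lower (adjusted p = 3.63e-06, and adjusted p = 0.424 with an estimated correlation). Toll-like receptor and NF-kB signalling had 14 of 32 lower, 7 higher and 11 not passing (8 higher and 14 lower adjusted over the list alone), with NFKBIA at −2.38 and ICAM1 at −1.57. Heat shock proteins had 11 of 27 lower, 4 higher and 12 not passing (4 higher and 11 lower adjusted over the list alone), with HSPH1 at −2.13. Of 26 complement genes 7 were lower, 2 higher and 17 did not pass (2 higher and 7 lower adjusted over the list alone), with C4BPB at −1.77 and MBL2 at −1.69. Of 37 interferon-stimulated genes 9 were lower, 3 higher and 25 did not pass (3 higher and 9 lower adjusted over the list alone), with IFI16 at −1.10. These 4 lists were called lower (adjusted p 0.0303, 0.0167, 0.0292 and 0.0292), with an adjusted p = 0.85, 0.976, 0.976 and 0.93 with an estimated correlation. The Toll-like receptor call ended without the array of cow 1112 before infection (adjusted p = 0.0533).

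Proteasome genes had 21 of 29 higher at 24 h than at 12 h, 0 lower and 8 not passing (22 higher adjusted over the list alone), with PSMD9 2.36-fold higher and PSMD5 at 0.97. Endoplasmic reticulum genes had 22 of 42 higher, 6 lower and 14 not passing (23 higher and 6 lower adjusted over the list alone), with SPCS3 at 1.30, SRPRA at 1.29 and ATF3 at −2.46. Both lists were called higher (adjusted p = 6.58e-06 and 0.0241), with an adjusted p = 0.724 and 0.976 with an estimated correlation. Without the array of cow 1112 before infection ribosomal proteins (adjusted p = 4.75e-10) and the respiratory chain (adjusted p = 0.00835) were called higher as well, and 0 lists with an estimated correlation (lowest adjusted p = 0.141).

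The last comparison asked which genes differed between 24 h and 192 h, in 11 cows. AKR1C3 rose by 5.70, CA3 by 4.85, FMO1 by 4.42, SLC10A1 by 4.18 and UGT2B10 by 3.69, each in 11 of 11 cows (adjusted p at most 5.9e-10). TNFRSF6B (−5.78), GPX3 (−4.97), S100A8 (−4.41), S100A12 (−4.33) and CTSL (−4.30) fell most, each in 11 of 11 cows. HP, SAA3 and LBP also fell (−2.01, −2.72 and −2.76), HP from a level close to the highest value of any array. Of all 9155 genes 1992 were higher at 192 h than at 24 h and 2759 lower. In total 10605 probe sets changed (44.2%), 5153 higher and 5452 lower, or 12129 without the array of cow 1112 before infection, 5844 higher and 6285 lower. Ribosomal centring, with a shift of 0.37, left 5307, 4413 higher and 894 lower. Without that array 16530 were higher and 2616 lower at a shift of 0.38. Of the 10674 probe sets changed at 24 h, 697 were also called at 192 h in their 24 h direction, or 900 of 11195 without that array; both contrasts use the same arrays before infection.

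Of 21 bile acid genes 19 were higher at 192 h than at 24 h, 0 lower and 2 did not pass (19 higher adjusted over the list alone), with SLCO2B1 at 3.48 and CYP7A1 at 3.32. Of 36 drug metabolism genes 28 were higher, 1 lower and 7 did not pass (28 higher and 2 lower adjusted over the list alone), with FMO5 at 3.48. Amino acid catabolism had 28 of 46 higher, 6 lower and 12 not passing (29 higher and 6 lower adjusted over the list alone), with FTCD at 2.63 and GNMT at −3.86. Fatty acid oxidation had 23 of 35 higher, 3 lower and 9 not passing (23 higher and 3 lower adjusted over the list alone), with ECI1 at 2.31. Of 19 cholesterol genes 13 were higher, 1 lower and 5 did not pass (13 higher and 1 lower adjusted over the list alone), with TM7SF2 at 2.20 and PMVK at −2.13. Fatty acid and triglyceride synthesis had 21 of 33 higher, 3 lower and 9 not passing (23 higher and 3 lower adjusted over the list alone), with THRSP at 3.26. Gluconeogenesis had 15 of 24 higher, 4 lower and 5 not passing (15 higher and 4 lower adjusted over the list alone), with TKFC at 2.94 and PCK1 at 2.39. These 7 lists were called higher, with adjusted p from 2.6e-10 for bile acid genes to 0.00107 for gluconeogenesis, and an adjusted p between 0.424 and 0.792 with an estimated correlation.

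Hepatocyte markers had 13 of 23 higher at 192 h than at 24 h, 1 lower and 9 not passing (14 higher and 1 lower adjusted over the list alone), with CYP2E1 at 2.74. Of 20 negative acute phase proteins 11 were higher, 0 lower and 9 did not pass (11 higher adjusted over the list alone), with HRG at 2.23 and SERPINA6 at 2.20. Stellate cell markers had 14 of 20 higher, 0 lower and 6 not passing (14 higher adjusted over the list alone), with COL1A2 at 2.42 and LUM at 1.64. Endothelial markers had 10 of 19 higher, 0 lower and 9 not passing (10 higher adjusted over the list alone), with STAB1 at 1.06. Of 21 T and NK cell markers 10 were higher, 1 lower and 10 did not pass (10 higher and 1 lower adjusted over the list alone), with ZAP70 at 0.66 and KLRK1 at 0.56. These 5 lists were called higher (adjusted p 0.000175, 0.00129, 0.000863, 0.0091 and 0.0283), with an adjusted p = 0.837, 0.87, 0.724, 0.784 and 0.837 with an estimated correlation.

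Endoplasmic reticulum genes had 35 of 42 lower at 192 h than at 24 h, 0 higher and 7 not passing (36 lower adjusted over the list alone), with CRELD2 at −2.96 and HYOU1 at −2.56. The proteasome had 24 of 29 lower, 0 higher and 5 not passing (25 lower adjusted over the list alone), with PSMB5 at −1.15 and PSMA1 at −1.14. IL-6 and JAK-STAT signalling had 17 of 30 lower, 3 higher and 10 not passing (3 higher and 17 lower adjusted over the list alone), with SOCS3 at −3.33 and IL1R2 at −2.78. These 3 lists were called lower (adjusted p = 3.42e-10, 1.86e-06 and 0.00276), with an adjusted p = 0.702, 0.716 and 0.702 with an estimated correlation. Without the array of cow 1112 before infection complement (adjusted p = 0.00666), interferon-stimulated genes (0.0463) and skeletal muscle markers (0.0368) were called higher, and ribosomal proteins (1.32e-06) and the respiratory chain (0.00553) lower, against 0 lists with an estimated correlation (lowest adjusted p = 0.141).

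With a correlation estimated from the data, camera called 0 of the 41 lists in each of the 5 comparisons. At an unadjusted p under 0.05 it gave 5 lists at 12 h, 1 at 24 h, 3 at 192 h, 4 for 24 h against 12 h and 1 for 192 h against 24 h. The preset correlation called 12, 16, 6, 16 and 15 lists and fry 12, 26, 4, 16 and 27. The camera calls therefore rest on the preset correlation. Fry does not use it but does not compare with other genes, and the counts of members depend on neither test.

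The 12 h and 24 h changes overlapped. Of the probe sets called at both times 2029 were higher and 1590 lower at both, 88 were higher at 12 h and lower at 24 h and 281 the reverse. Without the array of cow 1112 before infection these numbers were 2093, 2190, 108 and 424. With all arrays, lists of these sizes drawn independently share 744.9 higher and 600.5 lower. Both contrasts use the same arrays before infection. In simulated data without any change this sharing gave a correlation of r = 0.49 across probe sets, a covariance of 0.01 and an overlap of 0. The noise was simulated independently for each probe set and array, which set an overlap near 0 in advance. Shifts of a whole array, such as that of cow 1112 before infection, were left out, so the simulation may understate what shared arrays give. The observed values were r = 0.57 and a covariance of 0.14. With separate cows for each time, 6 for 12 h and 7 for 24 h over 20 random divisions, the mean overlap was 595.5 (13 to 1748), against 97.5 higher and 58 lower for lists of these sizes drawn independently, r was 0.47 (0.40 to 0.53) and the covariance 0.11. Probe sets are not independent replicates.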

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

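Of the tests in this part, the comparison of the stellate list with 4 other cell type lists and the test for skin, muscle or fat were chosen only after the result was seen, as were the ways of computing the standard errors of all tests.

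The effect at 24 h differed from the effect at 12 h in a direct test of the difference, in 8736 probe sets (36.4%). It also differed in 44 of 52 named genes, 18 higher and 26 lower at 24 h, most of which had been chosen for a large change at 12 h or 24 h, so that this share is not comparable with that over all probe sets. The largest differences were TNFRSF6B (4.23), CTSL (4.15), GPX3 (3.77), CLDN2 (2.91) and PDZK1IP1 (2.86) upwards and CA3 (−4.43), FMO1 (−3.93), SLC10A1 (−3.68), UOX (−3.32) and FMO5 (−3.32) downwards. Metabolic and hepatocyte lists differed with median differences of −1.19 (drug metabolism), −1.11 (bile acids), −0.79 (fatty acid oxidation), −0.75 (cholesterol), −0.67 (gluconeogenesis), −0.65 (amino acid catabolism), −0.49 (negative acute phase proteins), −0.47 (hepatocyte markers) and −0.28 (fatty acid and triglyceride synthesis). The medians of immune and stress lists differed by −0.26 (cytokines and chemokines), −0.24 (complement), −0.22 (heat shock proteins), −0.13 (interferon-stimulated genes) and −0.065 (Toll-like receptor and NF-kB signalling). The proteasome (0.54) and endoplasmic reticulum genes (0.67) stood higher at 24 h. With an estimated correlation camera called 0 of these lists, and the counts changed with ribosomal centring as described with the processing.

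The effect at 192 h differed from the effect at 24 h in 10605 probe sets. AKR1C3 (5.70), CA3 (4.85), FMO1 (4.42), SLC10A1 (4.18) and UGT2B10 (3.69) differed most upwards and TNFRSF6B (−5.78), GPX3 (−4.97), S100A8 (−4.41), S100A12 (−4.33) and CTSL (−4.30) downwards. List medians differed by −1.26 (endoplasmic reticulum), −0.70 (IL-6 and JAK-STAT signalling) and −0.65 (proteasome). Lists that stood higher at 192 h than at 24 h had median differences of 1.68 (bile acids), 1.25 (drug metabolism), 0.99 (cholesterol), 0.86 (fatty acid oxidation), 0.83 (amino acid catabolism), 0.75 (gluconeogenesis) and 0.53 (fatty acid and triglyceride synthesis). Among cell type and plasma protein lists the median differences were 0.67 (hepatocyte markers), 0.63 (stellate cells), 0.57 (negative acute phase proteins), 0.43 (endothelial cells) and 0.27 (T and NK cells). With an estimated correlation camera called 0 of these lists (lowest adjusted p = 0.424), and with ribosomal centring, at a shift of 0.37, 4413 probe sets were higher and 894 lower, against 5153 and 5452.

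Cow 2105 had a 24 h array only and was outside the comparisons. On it 10 of the 10 leading genes that rose at 24 h stood above every array before infection. The 10 leading genes that fell stood below every array before infection except that of cow 1112, whose RNA was degraded. TNFRSF6B stood at 11.19, against at most 5.44 before infection, and AKR1C3 at 3.98, against at least 10.63.

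Whether chance could give counts as large was examined on paired fits of 2 times, not on the joint model behind the 5 reported counts. Labels of the 2 times were exchanged within randomly drawn cows, with a paired fit of those 2 times, and 1 of 100 splits, the real one, reached the real count in each comparison. The real split called 5025 probe sets at 12 h, and the highest other split 3019. These numbers were 9068 and 3636 at 24 h, 1187 and 1 at 192 h, 9334 and 28 for 24 h against 12 h, and 11293 and 8443 for 192 h against 24 h. The median of the other splits was 0 in each comparison. With 100 splits no share under 1 of 100 could be reached, and the reported counts themselves were not tested in this way.

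The changes at 24 h are the first pattern with a technical explanation to weigh. For the cows other than 1112, RNA breakdown is argued against by the GAPDH difference, which changed by −0.04 (SE 0.14) within cows at 24 h. A mean change of at least 1 had been set as its mark. This does not cover the degraded array of cow 1112 before infection, which enters the reported 24 h changes. With that array 936 probe sets were higher and 918 lower by at least 2-fold, and without it 767 and 1058. A lower share of hepatocytes in the biopsies would raise the markers of all other cell types. Over 13 cows the 3 lists named for this test changed by −0.07 (SE 0.05, bile duct), 0 (SE 0.08, endothelial) and 0.19 (SE 0.09, stellate), or by −0.07 (SE 0.06), −0.05 (SE 0.08) and 0.11 (SE 0.06) without cow 1112, when T and NK cell markers changed by −0.14 (SE 0.06), which argues against it as the whole cause of the lower hepatocyte genes. A partly lower share, a response of the liver to the infection, and the time passed without uninfected cows for comparison, stay open.

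The difference between 12 h and 24 h could follow the time of day, because 12 h alone falls at another hour than the sample before infection. As the whole cause this predicts clock genes that change more at 12 h than at 24 h, but their median absolute change was larger at 24 h by 0.44 (SE 0.16), with 0.52 at 12 h and 0.96 at 24 h. Of 12 clock genes named beforehand 4 were measured, and infection itself may change clock genes. A part of the difference that follows the hour, and the progress of the response, stay open.

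The rise of stellate cell and fibroblast markers at 192 h was weighed against 3 technical explanations. A lower share of hepatocytes would raise other cell types alike, but the stellate median exceeded the mean of the endothelial, bile duct, macrophage and T cell medians by 0.71 (SE 0.16). Skin, muscle or fat in the biopsy, as far as these lists mark them, is argued against by their change of −0.06 (SE 0.05) on average. The skin list holds mainly keratin and cell junction genes, so these lists do not test for connective tissue taken up with the biopsy. For RNA breakdown, the fitted change at no GAPDH change was 1.3 (SE 0.23) over 11 cows, in a relation with r = −0.61 (permutation p = 0.047), rho = −0.47 (permutation p = 0.15) and r = −0.21 without the 2 cows farthest out, so the relation rests on those cows. Scar tissue at the site of an earlier biopsy, which was not tested, and a repair response of the liver both stay open.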

How the results depend on the processing

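Of the alternatives in this part, those without the array of cow 1112 before infection, those without the 4 arrays with a GAPDH difference above 2, and the scalings and array weights of the list tests were chosen after seeing the data. The number of arrays limits the precision.

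The counts stayed within 1.5 times the reported ones in all 5 comparisons with median or quantile scaling, an intensity trend, or the brighter part of the probe sets. At 12 h, at 24 h and in the later comparisons the same held for the choices of block and cows, and at 12 h they ran from 5025 to 5869. Over single genes and all alternatives 7945 results kept their direction and side of the threshold, 157 lost the call, 36 gained one and 8 reversed. For lists these numbers were 605 kept, 175 lost, 134 gained and 0 reversed.

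The count at 192 h depended on the pairing. Against 2464 it was 494 without the cow block, 1237 with cow as a random block, 1187 with the 2 times alone and 1064 with cows that had all 4 times. These use the pairing less or fewer arrays; arrays of 1 cow correlated with a median r of 0.26, and the estimated correlation was 0.12. SPP1, FOLR3, APON, TTPA, SAR1B, HM13, URAD, ALDH6A1, ABCF3, CYP4A22, LBP, CCNE1, MAD2L1, EDEM2, ERG and RPL35A did not pass without the block. Array weights gave 5716 and leaving out the 4 arrays with a large GAPDH difference 3803, and the share higher fell from 63.6% to 51.2% and 52.3%; the cause was not tested. At an adjusted p under 0.01 the count was 911. Changes of at least 2-fold numbered 806 at 12 h, 1854 at 24 h, 98 at 192 h, 1217 for 24 h against 12 h and 2237 for 192 h against 24 h.

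Leaving out 1 cow gave 5230 (without 1922) to 7002 (1112) at 12 h, 9977 (1586) to 11083 (1112) at 24 h, 1409 (1922) to 3149 (1867) at 192 h, with 1605 without 1920, 8010 (1586) to 10073 (1112) for 24 h against 12 h, 9793 (1385) to 11722 (1112) for 192 h against 24 h and 13367 (1586) to 15458 (1112) at any time.

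Ribosomal centring gave 2118 at 12 h, 17760 at 24 h, 99 at 192 h, 4010 for 24 h against 12 h and 5307 for 192 h against 24 h. The ribosomal list stood at −4.42 on the array of cow 1112 before infection, which this centring spreads over all probe sets, and the list itself was higher at 24 h. Without that array the counts were 19528 at 24 h, 19119 and 19146 in the later comparisons and 22336 at any time. The shift at 12 h and 192 h was −0.34 and −0.40 with all arrays, and 0.01 and −0.04 without that array. With centring, CD14, SLC39A14 and IL10 at 12 h lost their calls with all arrays but kept them without that array. Centring reversed CD14 at 12 h (−0.045), IL6 at 24 h (−0.74, or −0.32 without that array), RPL17 (−0.14) and RPL35A (−0.17) at 192 h and, without that array, CRP at 24 h (−0.02). The probe set of highest variance reversed ALB (0.28) and IGF1 (0.052) at 24 h; the cause was not tested.

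Camera with an estimated correlation called 0 lists in each comparison, with or without the array of cow 1112, with a lowest adjusted p of 0.18 and 0.141; the cause was not tested. At an unadjusted p under 0.05 it gave 5, 1, 3, 4 and 1 lists, or 5, 10, 2, 12 and 8 without that array. Fry, which does not compare with other genes, called 26 at 24 h and 27 for 192 h against 24 h. Of the lists, 6 were called at 192 h, and 11 without the array of cow 1112, 11 without the 4 arrays, 15 with ribosomal centring and 10 with array weights; the cause was not tested. Separate cows for 12 h and 24 h shared 595.5 probe sets (13 to 1748) against 3619, with fewer cows per time.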

Other observations

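The test of whether cows with a low 12 h response also had a low 24 h response was chosen only after the result was seen, and the genes named in this part were chosen after their values were seen unless the report names them.

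Some lists moved in both directions at 24 h and were not called. Their counts are to be read against those over all 9155 genes, of which 3177 were higher and 1748 lower at 24 h. In glycolysis and glucose uptake 12 of 24 genes rose, 4 fell and 8 did not pass (12 higher and 4 lower adjusted over the list alone, adjusted p = 0.777). ALDOA rose by 1.74, and PFKFB1 (−1.89) and PKLR (−1.80) fell. In the growth hormone and IGF axis 6 of 23 rose, 10 fell and 7 did not pass (8 higher and 10 lower adjusted over the list alone, adjusted p = 0.269), with FST at 2.05 and IGFALS at −1.88. Of 32 genes of oxidative stress and metallothioneins 13 rose, 6 fell and 13 did not pass (14 higher and 6 lower adjusted over the list alone, adjusted p = 0.456), and GPX1 rose by 2.44. At 12 h the metallothioneins MT1A and MT2A rose by 2.53 and 2.45. In antigen presentation 9 of 29 rose, 3 fell and 17 did not pass (9 higher and 3 lower adjusted over the list alone, adjusted p = 0.578), and neither share exceeded that of all genes.

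In coagulation and fibrinolysis 7 of 25 genes rose at 24 h, 4 fell and 14 did not pass (7 higher and 4 lower adjusted over the list alone, adjusted p = 0.936), with A2M at 3.01 and FGB at 1.33. Neither share exceeded that of all genes at 24 h. In the respiratory chain 27 of 70 rose, 1 fell and 42 did not pass (25 higher and 1 lower adjusted over the list alone, adjusted p = 0.124). The mean of its median within cows was 0.35, or 0.16 without cow 1112. Of 11 clock genes 3 rose at 12 h, 3 fell and 5 did not pass (3 higher and 3 lower adjusted over the list alone), with BHLHE40 at 2.46 and NFIL3 at 2.34. At 24 h 3 rose, 5 fell and 3 did not pass (3 higher and 5 lower adjusted over the list alone, adjusted p = 0.265), with HLF at −1.57 and PER2 at −1.46.

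Markers of macrophages and Kupffer cells, B and plasma cells, red cells, platelets and adipose tissue were not called in any of the 5 comparisons. At 192 h 1 of 17 macrophage genes was higher and 0 lower (adjusted p = 0.0902), 2 of 10 B and plasma cell genes (adjusted p = 0.765), 1 of 9 red cell genes (adjusted p = 0.194) and 1 of 6 platelet genes (adjusted p = 0.936), each with 0 lower, and 0 of 11 adipose genes higher with 1 lower (adjusted p = 0.382). IGHM rose by 0.91 and JCHAIN by 0.86 in the B and plasma cell list, and KRT19 by 0.92 in the bile duct list, calls that were not tried without single cows.

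The list changes at 12 h differed between cows. Over 12 cows the median standard deviation of the log2 values was 0.225 before infection, 0.264 at 12 h and 0.243 at 24 h, and 60% of probe sets had a larger one at 12 h than at 24 h. The endoplasmic reticulum list differed by −0.09 in cow 1415, −0.07 in cow 2428, 0.03 in cow 4351, 0.05 in cow 1867 and 0.06 in cow 1920 from the time before infection. At 12 h the arrays of cows 2428 and 1867 had the largest GAPDH differences, 2.53 and 2.44. Cows with a low 12 h response may also respond less at 24 h, and this was tested on the levels of 4 lists over 13 cows. Pearson's r was 0.32 for IL-6 and JAK-STAT signalling, 0.19 for Toll-like receptor and NF-kB signalling, −0.12 for heat shock proteins and −0.27 for endoplasmic reticulum genes (permutation p 0.28, 0.54, 0.69 and 0.38, adjusted p = 0.69 for each). Spearman's rho was 0.23, 0.23, −0.04 and −0.25 (permutation p 0.46, 0.46, 0.91 and 0.4, adjusted p 0.61, 0.61, 0.91 and 0.61). Without the 2 cows farthest out r was 0.23, −0.23, −0.28 and −0.05. The median r was 0.04. The SE set beside it, 0.32, is that of a single correlation over 13 cows and not of a median over 4 lists. It is too wide to decide, and levels do not take off the value before infection. In cows 1415 and 1920 the IL-6 list changed by 0.10 and 0.18 at 12 h and by 0.39 and 0.01 at 24 h. Their endoplasmic reticulum list changed by −0.09 and 0.06 at 12 h and by 0.95 in each at 24 h. CYP7A1, picked here after its values were seen, stood in these cows at 8.46 and 8.35 at 12 h and at 8.63 and 9.18 at 24 h.

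The array of cow 1112 before infection stood apart by list. Its medians differed from those of the other arrays before infection by −5.26 for negative acute phase proteins, −4.91 for acute phase proteins, −4.42 for ribosomal proteins, −3.84 for hepatocyte markers and −3.11 for the respiratory chain. The difference was −0.26 for stellate cell markers and 0.92 for neutrophil and for red cell markers.

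Only the genes named by the rule were looked at for probe sets that differ. For 5 of them, AKR1C4, CFTR, HSPA1A, PSMD6 and RPL26, a probe set other than the one with the highest mean was called in the opposite direction, each in at least 1 comparison.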
